A study of Mus musculus with 6 samples.

How the data were processed

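RNA from 6 samples of Wehi-231 cells, 3 labelled shCT and 3 labelled shTFII-I, was amplified to biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The deposited value table of the authors holds log2 intensities for 45281 probes. From the values, the columns had been quantile normalized between arrays, since their sorted values differ by at most 0.0012. The values show no sign of background subtraction, which leaves background in every intensity and makes differences of dim genes too small. Per the submitters' processing notes limma was used, with no version or role given. Background correction and probe filter are not given in the sources used here.

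A second table of bead signals and detection p-values has column headings that match no sample, so its 12 columns of per-sample values were not used. The plan fixed before the data were examined was to correct and normalize that table with neqc and to filter on detection p. It was replaced by the deposited log2 values without further normalization, and by a filter on an estimated background level. The mode of all deposited values, 6.45 on the log2 scale, was taken as the centre of the background, and the values below the mode were mirrored to give its upper side. A level of 6.61, which 1% of the background exceeds, was the limit. A probe was kept where it exceeded that level in at least 3 arrays, which left 12161 probes. Because the arrays share 1 distribution, the same number of probes lies above the level in each of them, and no array can be called brighter.

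Probes were named through the platform annotation, with 34885 probes carrying 1 gene symbol, 18 several and 10378 none. Of these, 34807 were matched by Entrez ID to current mouse gene symbols from the table of assembly GRCm38.p6, which served for names only. No coordinates are given, as no genome build goes with the array values. For each gene the probe with the highest mean over all 6 arrays was tested, 7227 genes in all, of which 2458 had more than 1 probe past the filter. Other probes past the filter are given for genes of the results where they had the other sign or a much smaller difference. A group in which no array exceeded the background level has only a bound, and folds are then given as at least the ratio of the brighter mean to the background level. Such a bound holds for the means of these arrays and leaves out their spread.

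The comparison of shTFII-I with shCT used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with constant prior variance), with p adjusted by Benjamini-Hochberg over all genes tested and a threshold of 0.05. Differences are log2 values, shTFII-I minus shCT, with the moderated standard error, and values for probes that were not tested or not chosen come from the same model fitted to all probes of the table or to all that passed the filter. Gene lists were fixed before the data were examined: 34 lists with 773 distinct genes, of which 496 were tested. The 28 lists with at least 3 measured genes were tested with camera, with a preset correlation of 0.01. With 3 arrays against 3 an exact permutation test cannot go below 0.1, so single genes were tested with limma alone. The median half-width of a 95% interval was 0.41 on the log2 scale.

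The rule for named genes, also fixed beforehand, took Gtf2i and, from genes past the threshold, the 12 largest rises and the 12 largest falls with groups apart. With fewer than 5 genes past the threshold it took the 10 with the smallest p, as values that did not pass. It also allowed up to 4 genes of smallest adjusted p from each list and all measured genes of the Gtf2i, CTCF and CDK8 lists. Other probes and genes named outside the rule are said to be so. The model was tested on simulated data, 20 sets with 200 changed genes each. Alternatives covered the filter, the prior variance, array weights, the choice of probe, the threshold, the set test, the replicate number as a block and each array left out. Normexp background correction with an offset of 16, other background levels, unnamed probes, 2 further prior settings and fry for change in either direction were added after the data were seen.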

Results

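Gene expression was measured in Wehi-231 cells, a mouse B cell lymphoma line, that carried one of 2 kinds of short hairpin RNA. The hairpin labelled shTFII-I is named for TFII-I, the transcription factor encoded by Gtf2i, and cells with the hairpin labelled shCT are the comparison group. There were 3 arrays in each group, 6 in all, and each array was an Illumina bead array hybridised with biotin-labelled cRNA. The series as a whole deals with the part of TFII-I in bringing CTCF to promoters, and the arrays ask which transcripts differ between cells with the 2 hairpins. Of 45281 probes, 12803 lay above the estimated background on each array, or 28.27%, and the number of arrays limits the precision of every difference. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

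Gtf2i, whose product the knockdown is named for, was not measurable with the probe named for it here. Whether any of the 10378 probes without a gene symbol detects Gtf2i was not known. Its only named probe, ILMN_3118216, lay below background on all 6 arrays. The log2 intensities were 6.47, 6.56 and 6.41 in the shCT arrays and 6.40, 6.53 and 6.44 in the shTFII-I arrays. The difference was -0.02 with a standard error of 0.06, and the knockdown could not be checked from it. Among the related genes of the same family, Gtf2ird1 differed by 0.38 ± 0.16 (log2, SE, shTFII-I minus shCT), with all shTFII-I arrays above all shCT arrays, and Gtf2ird2 by 0.22 ± 0.14. Neither passed limma's test over all genes (adjusted p = 0.745 and 0.826) or the test adjusted over the list alone. A second Gtf2ird1 probe differed by -0.07 and a second Gtf2ird2 probe by -0.12.

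The genes that separated the groups best were about 2-fold apart in the deposited values, and none of them passed the threshold. Cnr2, the cannabinoid receptor of immune cells, had a mean log2 intensity of 7.03 ± 0.11 (SD, n = 3) in shCT and 8.01 ± 0.17 (SD, n = 3) in shTFII-I cells, or 1.98-fold more. Its second probe gave nearly the same log2 difference, 0.99 against 0.98. Mt1, a metal-binding metallothionein, had means of 11.06 ± 0.21 in shCT and 12.06 ± 0.12 in shTFII-I cells (SD, n = 3 each), about 2-fold apart. Ftl1, the light chain of the iron store ferritin, had means of 9.86 ± 0.20 and 8.95 ± 0.09 (SD, n = 3 each), 1.89-fold lower in shTFII-I cells. Ly9, a receptor of the SLAM family on lymphocytes, was above background in the 3 shCT arrays at 7.26 ± 0.15 (SD, n = 3) and in none of the shTFII-I arrays. Its mean in these arrays was therefore at least 1.57-fold lower, taking the background level as the lowest measurable signal.

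The other 6 of the 10 genes with the smallest p likewise had all arrays of one group above all arrays of the other. Differences (log2, with SE) were 0.98 ± 0.13 for Ankrd49, 0.91 ± 0.13 for Lmcd1, 0.91 ± 0.14 for Rab8b, which encodes a small GTPase, and 0.90 ± 0.14 for Arhgap8. They were 0.77 ± 0.12 for Plekha1 and -0.76 ± 0.11 for Abcf1, an ABC protein that acts in translation. All 3 Lmcd1 probes pointed the same way, with differences of 0.91, 1.16 and 0.62. For Rab8b the second probe differed by -0.21, and for Abcf1 the other probes differed by 0.21 and -0.23. The second probes of Arhgap8, Plekha1 and Ly9, all dimmer, differed by less, at 0.09, 0.18 and -0.25. All 10 genes had the same adjusted p in limma, 0.255.

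With limma's constant prior variance, as fixed before the data were examined, 0 of 7227 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 479 genes, 223 higher and 256 lower in shTFII-I cells, where 361 would be expected with no effect. The groups did not overlap in 857 genes, 11.9% of those tested, against 10% by chance. When limma's prior was allowed to follow intensity and made robust, 6 genes passed: Cnr2, Aldh3b1 and Arhgap8 higher, and Sdr39u1, Ly9 and Egfl7 lower. Their adjusted p in limma ran from 0.000111 for Sdr39u1 to 0.0482 for Cnr2, which did not pass with the trend only or with normexp alone. Of the 6 genes, Aldh3b1, Sdr39u1 and Egfl7 lie outside the naming rule and were chosen after their values were seen. The SDs of these genes differed between the groups (n = 3 each), with 0.034 in shCT and 0.632 in shTFII-I arrays for Aldh3b1. For Sdr39u1 they were 0.406 and 0.038, and for Egfl7 0.374 and 0.019. For Cnr2, Ly9 and Arhgap8 the SDs ran from 0.079 to 0.175. With the constant prior, Aldh3b1, an aldehyde dehydrogenase, differed by 1.48 ± 0.29 (log2, SE), with 0.41 on its second probe, and Egfl7 by -1.17 ± 0.20. With the prior that called them, the SEs of Aldh3b1 and Egfl7 were 0.24 and 0.23. Sdr39u1 was not above background in any shTFII-I array and was at least 1.98-fold lower in the mean. These sizes depend on the background left in the deposited values: with normexp background correction Cnr2 was 2.86-fold, Arhgap8 3.01-fold and Aldh3b1 5-fold higher (log2 difference 2.32), and Egfl7 was 3.28-fold lower (-1.71). For Ly9 and Sdr39u1 normexp gave 3.75-fold and 6.11-fold lower, from shTFII-I values that lie below background.

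**Figure D1:**
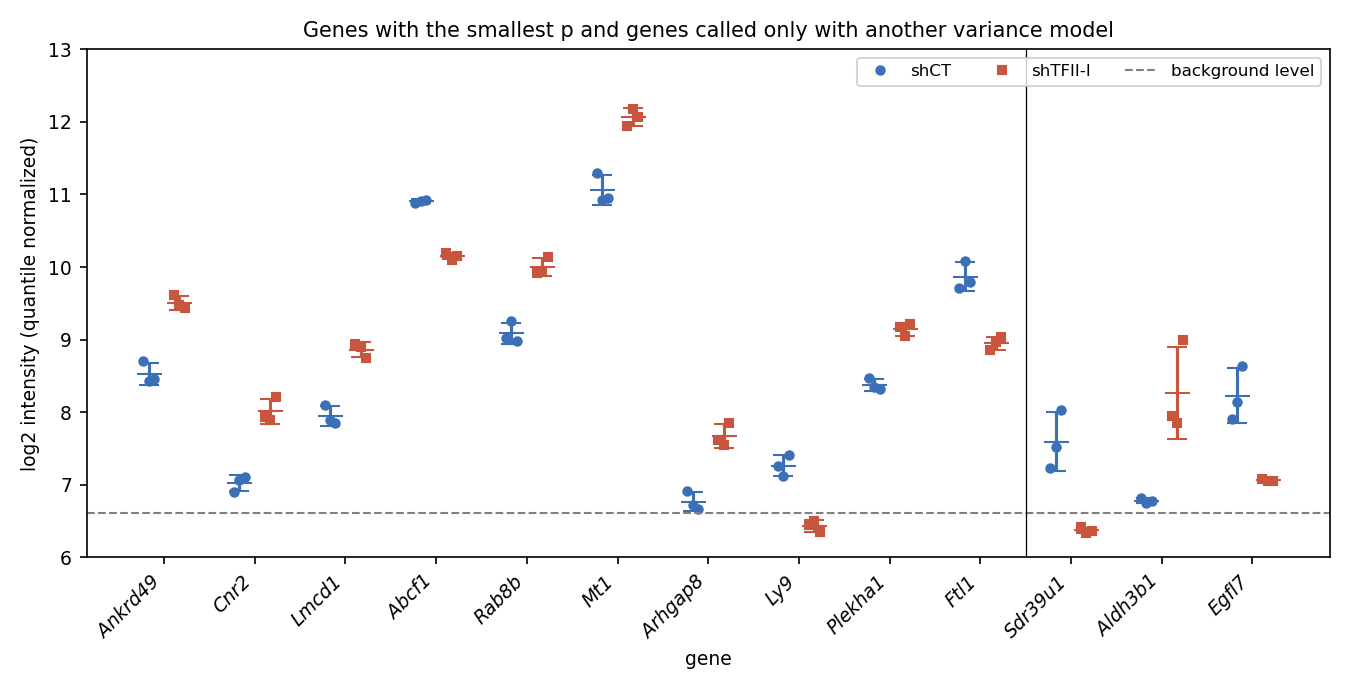
Log2 intensity (vertical axis) of 13 genes (horizontal axis) in each array, circles for shCT and squares for shTFII-I, with the group mean and SD; the dashed line is the background level. Left of the vertical line are the 10 genes with the smallest p, none past the threshold with a constant prior variance, and on the right are Sdr39u1, Aldh3b1 and Egfl7, which passed with an intensity-dependent prior.

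The genes of CTCF and cohesin, the complex that works with CTCF, showed no shift that passed the test. Ctcf itself differed by 0.07 ± 0.26 (log2, SE) between the groups, a difference smaller than its error. Of 13 measured members of the list, 8 were higher in the mean and 5 lower, with a median log2 difference of 0.10 (camera adjusted p = 0.745). The cohesin loader Nipbl differed by 0.48 ± 0.24, but its 7 measured probes ranged from -0.27 to 0.63. Esco2, a cohesin acetyltransferase, differed by 0.32 ± 0.17, and the deacetylase Hdac8 by -0.21 ± 0.14. In the CDK8 module of Mediator, with 4 members measured, Cdk19 differed by 0.41 ± 0.22, Cdk8 by 0.17 ± 0.25, Ccnc by -0.42 ± 0.22 and Med12 by -0.31 ± 0.17 (camera adjusted p = 0.875). A second Cdk19 probe differed by -0.16, and the other Ccnc probes by 0.07, -0.15 and -0.01. In the Mediator core 11 members were higher and 13 lower, among them Med25 at -0.67 ± 0.20, with 0.0032 on its second probe, and Med10 at 0.57 ± 0.29 (camera adjusted p = 0.875). General factors of RNA polymerase II were split 15 to 14, with Gtf2e2 at 0.53 ± 0.18 and Gtf2f1 at -0.56 ± 0.26 (camera adjusted p = 0.875).

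Among genes of B cells, 1 gene in each of 2 lists passed when adjusted over the list alone. Fcgr2b, the inhibitory Fc receptor, was at 8.47 ± 0.09 in shCT and 7.72 ± 0.21 (SD, n = 3 each) in shTFII-I cells, 1.68-fold lower. Its adjusted p was 0.0263 over the list of B cell receptor signaling and 0.374 over all genes in limma. Its other 2 probes, both near background, differed by -0.12 and -0.06. Vpreb3, which belongs with the pre-B cell receptor, was at 7.81 ± 0.29 and 8.57 ± 0.20 (SD, n = 3 each), 1.69-fold higher. Its adjusted p in limma was 0.009 over the list of pro-B and pre-B markers, of which Igll1 (-0.12) was the only other gene measured, and 0.473 over all genes. In the list of B cell identity, which also holds Vpreb3, 14 genes were higher and 9 lower, with Irf8 at 0.28 ± 0.14 (camera adjusted p = 0.547), and 0 passed when adjusted over the list alone. Receptor signaling genes as a list went both ways, 10 higher and 9 lower (camera adjusted p = 0.875). Plasma cell genes were lower in 8 of 10, among them Mzb1 at -0.41 ± 0.34 and Slamf7 at -0.33 ± 0.18 (camera adjusted p = 0.547).

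Genes of antigen presentation by MHC class II were higher in 6 of 9, with a median of 0.08 (camera adjusted p = 0.57). Cd74, the invariant chain, differed by 0.72 ± 0.25, but its other probes differed by 0.14 and 0.16. H2-Eb1 was above background in the shTFII-I arrays alone and at least 1.15-fold higher in the mean (limma adjusted p = 0.657 over all genes). The list with the smallest camera p was that of immediate early genes, in which 16 of 18 were higher, with a median of 0.09. Its unadjusted p of 0.028 became 0.547 after adjustment. Dusp6 differed by 0.36 ± 0.13, Egr1 by 0.35 ± 0.18, and Klf6 by -0.36 ± 0.14. Of the NF-kB targets 12 were higher and 7 lower, with Tnf at 0.52 ± 0.15 and 0.33 on its second probe, and Cd83 at -0.58 ± 0.20 (camera adjusted p = 0.547). Interferon response genes were higher in 6 and lower in 9, with Irf9 at 0.32 ± 0.13 and 0.05 on its second probe (camera adjusted p = 0.875).

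Histone genes were lower in 10 of 15, with a median of -0.13 (camera adjusted p = 0.547). H1f2, a linker histone, was at 8.04 ± 0.15 in shCT and 7.45 ± 0.07 (SD, n = 3 each) in shTFII-I cells. It passed limma's test when adjusted over the list alone (adjusted p = 0.0392) and not over all genes (0.435), and its second probe differed by -0.35. H2ac11 differed the other way, by 0.55 ± 0.22. S phase genes were split evenly, 16 to 16, with Fen1 at -0.37 ± 0.12 (camera adjusted p = 0.745). Genes of nucleotide synthesis were lower in 12 of 22, with Rrm2 at -0.37 ± 0.14 and -0.72 on its second probe, and Tk1 at -0.63 ± 0.24 and -0.21 (camera adjusted p = 0.547). Genes of G2 and mitosis were lower in 12 of 22, and Aurka differed by 1.10 ± 0.36 with overlapping groups (camera adjusted p = 0.875). Probes of Cdc20 went both ways, from -0.43 to 0.66.

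In the stress and metabolic lists the members went both ways as well. The ATF4 list of amino acid synthesis and stress was lower in 11 of 19, with Mthfd2 at -0.45 ± 0.17 and Atf5 at -0.41 ± 0.17 (camera adjusted p = 0.547). Without the third shTFII-I array this list passed, with an adjusted p of 0.021, which was 0.661 with an estimated correlation. Endoplasmic reticulum stress genes were lower in 15 of 22, with Syvn1 at -0.72 ± 0.24 and Hsp90b1 at 0.72 ± 0.41 (camera adjusted p = 0.57). Glycolysis genes were higher in 10 of 13, with Ldha at 0.42 ± 0.32 (camera adjusted p = 0.547). Oxidative phosphorylation genes were lower in 19 of 35, with Ndufc1 at -0.73 ± 0.24 and -0.10 on its second probe (camera adjusted p = 0.668). Adjusted p was 0.875 for the lists of the citric acid cycle (10 higher, 9 lower), hypoxia (5 and 7), cholesterol synthesis (9 and 8), heat shock (4 and 7), ribosomal proteins (14 and 11) and RNA interference (5 and 5). It was 0.745 for p53 targets (7 higher, 10 lower) and for MYC-driven ribosome biogenesis (12 and 13), and 0.991 for the BCL2 family (5 and 4). In the last of these Bid differed by 0.25 ± 0.20 and Bcl2 by -0.10 ± 0.14, with its other probes between -0.14 and 0.0035.

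Markers of other cell types were mostly not measurable. For each of 4 such lists 2 genes passed the filter, too few for a list test. Their levels differed widely: mean log2 intensity in shCT arrays was 11.80 for Tfrc, 10.47 for Cd8b1 and 8.81 for Zap70. For Tyrobp, Csf1r, Klf1 and Acta2 it was 6.55 to 6.60, close to the background level. The T cell genes Zap70 and Cd8b1 differed by -0.61 ± 0.32 and -0.05 ± 0.32. Other Zap70 probes differed by -0.34 and 0.18, and other Cd8b1 probes by -0.18 and -0.30. The myeloid genes Tyrobp and Csf1r differed by 0.12 ± 0.13 and 0.02 ± 0.12. Tfrc and Klf1, from the erythroid list, differed by 0.20 ± 0.15 and -0.01 ± 0.12. Vim and Acta2, from the fibroblast list, differed by -0.18 ± 0.18 and 0.05 ± 0.15. Whether the measured genes of these lists are specific to the named cell types was not tested. None of these genes passed over all genes or when adjusted over the list alone. Across all 28 lists that could be tested, 0 passed camera in limma with a preset or an estimated correlation, and 1 had an unadjusted p under 0.05, the immediate early genes (p = 0.109 with an estimated correlation). The other set test in limma, fry, called 0 lists for genes moving, on balance, one way. Its unadjusted p was under 0.05 for B cell identity and for histone genes, both with an adjusted p of 0.445. For change in either direction, a test added after the data were seen, fry called 1 list, the histone genes (limma adjusted p = 0.00228). Without H1f2 the unadjusted fry p of that list was 0.113. With 1 array left out its adjusted p ran from 0.0451 to 0.929, and it stayed under 0.05 only without the third shCT array. Other lists passed this fry test without the first shTFII-I array (2 lists) and without the third (1 list). With all arrays the MHC class II and immediate early genes had adjusted p of 0.189 and 0.252 in the same fry test. Apart from Fcgr2b, Vpreb3 and H1f2, 0 list genes passed when adjusted over the list alone.

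**Figure D2:**
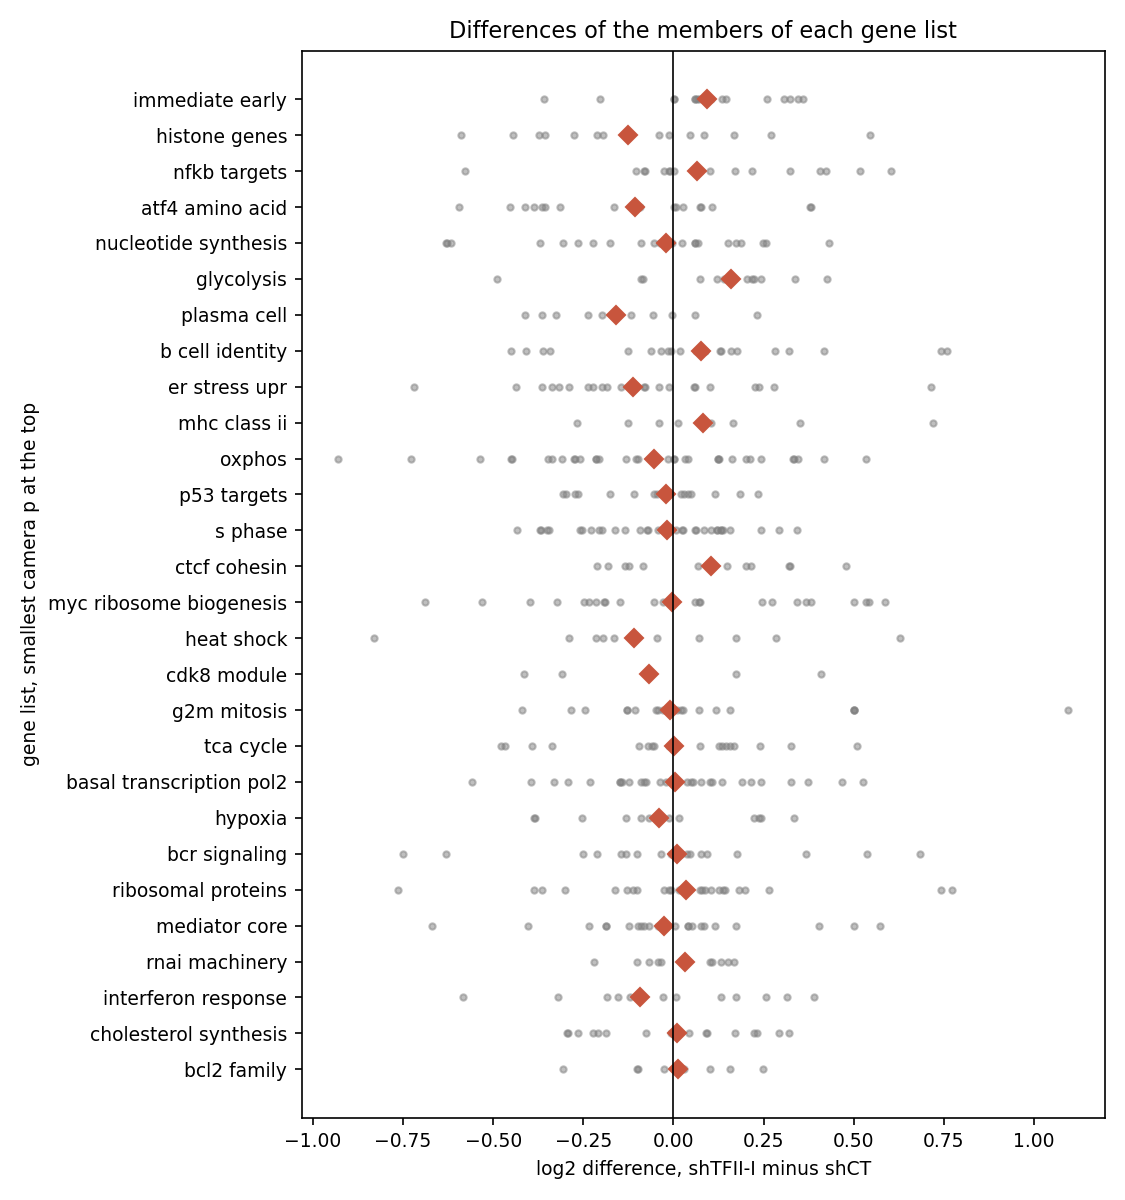
Log2 difference between shTFII-I and shCT (horizontal axis) for the measured members of each of 28 gene lists (vertical axis), grey points for genes and a red diamond for the median. Members lie on both sides of 0 in every list, and 0 lists passed the threshold with camera.

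Replicates of one group were about as alike as arrays of different groups. The most alike pair joined the second shCT array and the first shTFII-I array, with a Pearson r of 0.978 over 7227 genes, which are not independent replicates. Within groups r ran from 0.939 to 0.969, and between groups from 0.939 to 0.978. The second shCT array was the closest array to each of the other 5. The groups took up 22.25% of the variance of all genes, against 20% expected with no effect. In simulated sets with 200 changed genes each, 74.3% of genes changed by 1 on the log2 scale were recovered. For changes of 1.5 and 0.5 the shares were 96.4% and 6.72%. A median of 126.5 genes was called per set, and with so many calls the adjusted threshold is easier to pass. In the deposited values 17 genes were at least 2-fold apart and 0 passed. The shares therefore do not give the chance of calling a 2-fold change in these data.

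**Figure D3:**
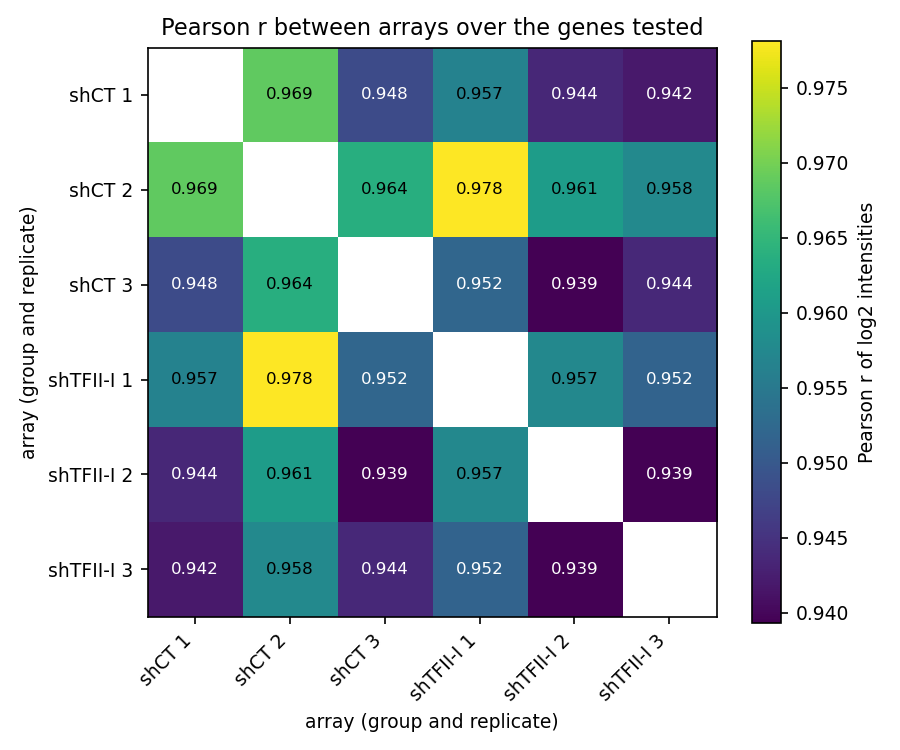
Pearson r of log2 intensities between each pair of the 6 arrays, both axes listing group and replicate, with colour and printed values giving r. The pair of shCT replicate 2 and shTFII-I replicate 1 has the highest value, 0.978.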

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

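Settings that needed the table of bead signals were not run: neqc with quantile or median scaling, the log2 of its signals plus 16, and filters on detection p. Slides as a block were not run, since none are given; Gtf2i has 1 named probe, and leaving it out of the list tests moves nothing, since it was not tested. The alternatives chosen after the data were seen were normexp, above background in all arrays, the looser background level, unnamed probes, the prior with trend only, normexp with trend and robust, and fry for change in either direction. The count of 0 genes became 6 with a prior that followed intensity and was robust, 5 with the trend only, 5 with normexp, and 6 with normexp, trend and robust. The 5 genes of normexp were all among the 6 of the prior with trend and robust; the residual SD rose with intensity, from a median of 0.116 in the dimmest 1807 genes to 0.365 in the brightest 1807. The count at unadjusted p under 0.05 went from 479 to 1011 without a filter, to 653 genes with every named probe tested and to 791 probes with unnamed ones as well, as more were tested, and ran from 352 to 541 with 1 array left out. With the replicate number as a block 0 genes passed (511 at unadjusted p under 0.05). Same-numbered arrays deviated with correlations of -0.01, 0.003 and 0.10, against -0.11 to 0.13 for the other pairs between groups. These values show no pairing by number, but cannot exclude it, since noise of single probes could hide a shared deviation. With 1 array left out 0 genes passed, and the lists past the threshold with camera ran from 0 to 1, the ATF4 list without shTFII-I replicate 3. With fry for change in either direction and all arrays 1 list passed, the histone genes, a call that rested on H1f2. With 1 array left out that fry test called 0 to 2 lists. Below background, Gtf2i ran from -0.06 to 0.015 with 1 array left out, and was -0.07 with array weights and -0.08 with normexp. Small differences changed sign; with array weights Cdk8 was -0.026, Csf1r -0.0042 and Klf1 0.026, and with the mean of the probes Tnrc6a was 0.12, against -0.22. With 1 array left out Cdk8 ran from -0.0018 to 0.43, Csf1r from -0.014 to 0.054, Klf1 from -0.053 to 0.015, Bbc3 from -0.51 to 0.016, Cd8b1 from -0.35 to 0.19, Bcl2 from -0.18 to 0.0059, Bad from -0.21 to 0.034, Xpo5 from -0.0056 to 0.25 and Acta2 from -0.062 to 0.12. The cause of these was not tested. The other settings left 0 genes and 0 lists past the threshold.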

Other observations

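The genes of this paragraph were chosen after their values were seen, and none passed limma's test over all genes. Both genes of the TAPP adaptors, which bind a phosphoinositide made after receptor signaling, were higher in every shTFII-I array than in every shCT array. Plekha2 had means of 9.89 ± 0.18 and 11.03 ± 0.29 (SD, n = 3 each), 2.21-fold higher, and Plekha1 was described with the genes of smallest p. Cyth4, a cytohesin, and Cytip, which encodes a cytohesin-binding protein, differed by -1.31 and -1.03 on the log2 scale, the second with overlapping groups. Other genes at least 2-fold lower in the mean were Prelid3b (-1.42 ± 0.33, log2 and SE), Snrnp25 (-1.29 ± 0.25), Jagn1, Psmd8, Rpn2, Calm3 and Tbc1d10c, whose 4 probes ranged from -1.02 to 0.02. In all, 6 genes were at least 2-fold higher and 11 lower in the deposited values, 17 together, against 63 after normexp background correction. Among 1546 probes past the filter without a gene name here, 2 stood wider apart than any of these genes: ILMN_2476405 had means of 6.74 and 8.62, and ILMN_2642462 of 9.62 and 7.63 (limma adjusted p = 0.262 for both, over all 12161 probes).

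The probe noise test, the ratio of mean squares and the split counts for the intensity-dependent prior and for fry were chosen after their results were seen, and normexp after the data were. The first pattern is that 0 genes passed with a constant prior. Exchanging the labels of shCT replicate 2 and shTFII-I replicate 1 lowered the genes at unadjusted p under 0.05 from 479 to 284. That is by more than the SD of the other splits (73.9). The test cannot decide about an exchange, since the other splits, whose groups are mixed, themselves ran from 279 to 496. Normexp brought 5 genes past the threshold, which background hiding some differences would also do. The trend alone, with no correction, called the same 5, so the prior matters. With trend and robust the same 6 genes passed with and without normexp, so there the correction added none. The counts therefore do not decide whether background hides differences. The 10 splits of 6 arrays are too few to exclude chance: 2 splits, the real one included, gave at least 479 genes, the highest other giving 496. With the intensity-dependent prior 1 split, the real one, gave 6 genes, and the highest other gave 0.

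The second pattern is that probes of one gene often gave different differences. Over 2458 genes the deviations of the 2 brightest probes from their group means correlated across arrays with a median r of 0.092, against -0.002 for random pairs, consistent with independent noise of each probe. Closeness to background does not account for it, since the median was 0.059 for 207 genes with both probes over 9. A change of transcript forms with the knockdown is not its main source. The mean square between the groups of the difference of 2 probes, summed over genes, was 0.929 times that within groups. The 95% interval, from resampled genes, was 0.863 to 0.998 and leaves out the spread between arrays. The ratio was at most 1.06 with 1 array left out and 0.928 to 1.08 in the other splits, where a main source needs over 2. The median r within the shCT arrays alone was 0.093. That value cannot bear on the knockdown, since deviations within a group hold no difference between the groups. Changes of transcript forms in single genes stay open, as does what makes the probe noise. No test here separates the bead signal from the labelling.

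The third pattern is the likeness of shCT replicate 2 and shTFII-I replicate 1. If each array carries its own amount of independent noise, the distance of a pair is the sum of 2 array terms, and this pair lay -1.21 SD from the sum fitted to the other pairs. That is what 2 arrays of low noise would give. Both also have the highest array weights, 2.25 and 1.40, but the weights rest on the same values and add no separate evidence. A difference in the knockdown between cultures was not tested, since the only named Gtf2i probe lay below background.

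Tests of 3 hypotheses followed from single genes, with no correction for their number. Gsto1 (-0.88 ± 0.15) and Gstt1 (-0.94 ± 0.19) were both among the 30 smallest p, and of 8 other glutathione S-transferase genes 7 were lower, with a median of -0.16 (camera p = 0.00759, and p = 0.0522 with an estimated correlation). The family may be lower in shTFII-I cells, as a hypothesis; Gsta4 differed by -0.51 ± 0.19 and Gstz1 by -0.53 ± 0.23, and the camera p with 1 array left out ran from 0.0075 to 0.0458. For metallothioneins as a group no answer was had, as Mt2 differed by 0.0718 close to background. Genes whose 2 brightest probes both had an unadjusted p under 0.05 in one direction numbered 20, and the highest other split gave 13, with too few splits to exclude chance. They include Cnr2, Lmcd1, Ly9, Aldh3b1, Tnf and Rrm2, and Cbr3, a carbonyl reductase, at -0.65 and -0.56, chosen after its values were seen. For the histone list too the splits are too few to exclude chance. Its unadjusted p with fry for change in either direction was 8.13e-05 in the real split. In the other splits it ran from 0.408 to 0.813. Counting any list, 3 splits, the real one included, called at least 1 list, and the highest other called 1.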
